A study of Mus musculus with 14 samples.

How the data were processed

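The series measured a mouse cell line that the labels call LEPC (strain C57BL/6, 3 passages) in 3 conditions, a control labelled scr, overexpression of miR-93-5p, and overexpression of a mutated miR-93-5p, called mutant here. Of the 14 samples, 3 were RNA-seq libraries, 3 were libraries of mRNAs recovered with the microRNA (called pulldown here, for which the series text mentions biotin in the miR-93-5p group), and 8 were chromatin immunoprecipitation samples of scr and miR-93-5p cells for H3K4me3, H3K27me3, H3K9me3 and input. The 2 input samples were not analysed here. Every combination of assay and condition had 1 library, so there was no replicate error, no test between conditions and no p-value, and every difference below is a difference between libraries.

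The RNA-seq and pulldown values are FPKM per assembled locus, with a lower and an upper bound for each, per the file headers. TopHat2, Cufflinks and Cuffdiff were used on mm9 for the RNA data, and CASAVA 1.4, Bowtie and MACS were also named, per the submitters' processing notes, which give no settings. The loci of each library were assembled from its own reads and carry numbers in place of gene names. The deposited peak lists give a score for each peak of each library separately, from 50 upward. Scores of peak callers depend on depth as well as on enrichment and were not compared between libraries as signal.

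The genome build was checked against gene ends. Locus ends that lay on a gene end or within a few bp of it were counted. In the RNA-seq libraries these numbered between 913 and 1031 for mm9 gene ends and between 31 and 34 for GRCm38 gene ends. In the pulldown libraries they numbered between 20 and 31 for mm9 and between 601 and 712 for GRCm38. Pulldown loci were therefore named through a GRCm38.p6 gene table, used for names only, although the processing notes give mm9. RNA-seq loci and peaks were named through 35640 mm9 gene loci that the pulldown files list at an FPKM of 0. Of their 35620 identifiers 31006 had a symbol, and 18479 protein-coding symbols were used. No strand is given for these loci, so a mark was assigned to a gene where a peak overlapped the gene locus by at least 1 bp, and not by promoter.

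A locus and a gene were matched where each was the other's best overlap and the shared length was at least 0.5 of their joint length, a rule set after the files were seen. No symbol then had 2 loci to sum. Protein-coding genes matched in all 3 libraries of an assay, with a mean FPKM of at least 1, were compared, 8414 in RNA-seq and 5241 in the pulldown. Ratios are log2 of FPKM plus a pseudocount of 1. A gene counted as changed in miR-93-5p when it differed at least 2-fold in the same direction from scr and from mutant. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 was used, and matplotlib 3.10.9 for the figures.

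FPKM divides fragments by the length of a transcript model, and the models differed between libraries because each was assembled alone. A second measure was therefore computed after the files were seen. The number of fragments whose counting error would give the deposited bounds, called implied fragments, does not depend on that length. Of loci with fewer than 40 implied fragments, between 56.0% and 60.1% per library lay within 0.1 of a whole number. Bounds also widen where fragments are shared between isoforms, so an implied number can lie below the real one. Implied fragments were scaled to a median ratio of 1 and compared with 10 added, over 8115 RNA-seq and 4947 pulldown genes with at least 3 in each library. Summed over loci they came to 14589703, 15301760 and 19513878 in the scr, miR-93-5p and mutant RNA-seq libraries and to 5322228, 3814082 and 5855468 in the pulldown libraries. The median counting error of a log2 ratio over scr for miR-93-5p was 0.06 in RNA-seq and 0.12 in the pulldown, and it covers counting alone.

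The gene lists, the thresholds, the rule for named genes and most alternatives were fixed before the data were examined. The named genes were the 10 with the largest rise and the 10 with the largest fall over scr among changed RNA-seq genes, the 15 most enriched and 5 most depleted pulldown genes, up to 4 members per gene list with the largest ratio over scr in either direction, the 5 highest-scoring peaks per mark found in each condition alone, and always Cdkn1a and Mcm7, the host gene of the microRNA. There were 27 lists: reported targets of miR-93-5p or its miR-17 family, classical tumour suppressors, PI3K-Akt-mTOR, TGF-beta and BMP, Wnt and Hippo signalling, p53 response, apoptosis regulators, cell cycle and replication, methylases and demethylases of H3K4, H3K27 and H3K9, Polycomb and DNA methylation, microRNA machinery, markers of hepatocytes, biliary and progenitor cells, endothelium and leukocytes, mesenchymal and matrix genes, interferon response, inflammation, unfolded protein and amino acid stress, glycolysis and hypoxia, cholesterol and fatty acid synthesis, ribosomal proteins, mitochondrial transcripts and abundant constitutive genes. A list with at least 5 measured genes was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size matched on mean FPKM in 10 bins. A list was said to stand apart below percentile 2.5 or above 97.5. Genes are not replicates, so a percentile describes these libraries only.

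The steps were tested on simulated data. With loci cut from known genes, 2000 of 2000 RNA-seq genes and 1996 of 2000 pulldown genes were matched to the right gene. These loci kept most of their gene, so all could pass the overlap limit. Real loci were often shorter pieces, with a median span of 2121 bp in the miR-93-5p pulldown, and their matching was not measured this way. With 200 changed genes among 8115 in a simulated RNA-seq comparison, 47 of 50 with a 2.5-fold rise, 50 of 50 with a 4-fold rise, 50 of 50 with an 8-fold rise and 49 of 50 with a fall to 0.25 were called, with 2 of 7915 unchanged genes. In the simulated pulldown comparison of 4947 genes the same sizes gave 47, 50, 50 and 47 of 50, with 8 of 4747 unchanged genes called. The simulated values held counting noise alone. Transcript models did not differ between the simulated libraries, so false calls from such differences were not measured.

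Alternatives to the pseudocount, the filter on FPKM, the scaling, the matching of random lists, the score threshold, the overlap that counts as shared and the gene window were tried, as were other matching limits, genes of every biotype, implied fragments, peak midpoints and the removal of the scr or mutant library. A search for seed matches of miR-93-5p in transcripts was not run, since no sequence or annotated UTR of either build was at hand. Expression of the microRNA itself was not analysed here.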

Results

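RNA-seq, pulldown and histone mark libraries of LEPC cells were compared between the scr control, miR-93-5p overexpression and overexpression of the mutant microRNA, with 1 library each. miR-93-5p is a microRNA of the miR-17 family, which lowers the level or translation of mRNAs that pair with it, and the series presents it as a driver of liver cancer acting on tumour suppressors and epigenetic pathways. The RNA-seq libraries held 18328, 16822 and 18076 assembled loci in scr, miR-93-5p and mutant, and the pulldown libraries 15302, 18031 and 14815. No value has a replicate error. The bounds beside an FPKM are those the files give for that library.

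The first comparison asked which mRNAs differed in miR-93-5p from both scr and mutant. Of 8414 genes, 56 were at least 2-fold higher and 73 at least 2-fold lower in miR-93-5p than in both other libraries. Ifitm1, which encodes an interferon-induced transmembrane protein (mm9 chromosome 7, 148153119 to 148155724), stood at 163 FPKM (154 to 172) against 5.41 (4.19 to 6.63) in scr and 22.9 (20.5 to 25.4) in mutant. Scara5, a scavenger receptor gene (chromosome 14, 66285239 to 66383663), was at 29.9 FPKM against 1.16 in scr and 3.98 in mutant. The chemokine gene Cxcl3 was at 44.9 FPKM against 4.55 and 18.3, Enpp2, which encodes autotaxin, at 17.2 against 2.72 and 4.37, and the kinase gene Dclk1 at 6.34 against 0.662 and 1.37. The log2 ratios of these 5 genes over scr lay between 2.14 and 4.68. In the mutant, Ifitm1, Scara5 and Cxcl3 were also at least 2-fold above scr.

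The gene with the largest fall over scr was Foxj1, a transcription factor of motile cilia (chromosome 11, 116192017 to 116196713), at 0.935 FPKM (0.660 to 1.21) against 29.3 (27.9 to 30.8) in scr and 5.08 (4.62 to 5.54) in mutant. Spag1, needed for the assembly of ciliary dynein, was at 2.23 FPKM against 32.5 and 7.51. Apob, the structural protein of liver lipoproteins, was at 2.54 against 29.1 and 10.0. The helicase-like gene Dqx1 was at 5.23 against 65.0 and 87.1, Gimd1 at 2.02 against 23.3 and 17.6, Anks4b, a gene of microvilli, at 2.38 against 18.8 and 17.4, and the histidine catabolism gene Amdhd1 at 0.817 against 9.58 and 2.99. Foxj1, Spag1, Apob and Amdhd1 were also at least 2-fold below scr in the mutant.

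Some of these differences were in FPKM and not in implied fragments. Anapc11, a subunit of the anaphase-promoting complex, was at 128 FPKM against 20.1 in scr and 15.8 in mutant, while its implied fragments were 807, 1157 and 1237. Thymidine kinase Tk1 was at 161 FPKM against 26.1 and 30.1 with 1600, 1463 and 1711 implied fragments. Ndufs6, a subunit of respiratory complex I, and Ifitm3 were higher in FPKM with log2 ratios over scr of 1.81 and 1.79 and of 0.20 and 0.28 in implied fragments. Arpp19 was at 33.4 FPKM against 216 and 157, and its implied fragments were 1713, 763 and 1167. 1700016C15Rik was lower in FPKM at a log2 ratio of -2.72 over scr, and at -0.53 over scr in implied fragments. Tma7 was at -2.59 over scr in FPKM and at -0.99 in implied fragments, just under the 2-fold limit. Its mutant value had wide bounds (83.2 to 173 FPKM) and 32.7 implied fragments, which put its log2 ratio over mutant at 5.02 in that measure. Thada was at 19.8 FPKM against 4.62 and 8.91, with no usable bound in the mutant library. In all, 17 of the higher and 37 of the lower genes also differed at least 2-fold from both other libraries in implied fragments, among them Ifitm1, Scara5, Cxcl3, Enpp2 and Dclk1, and Foxj1, Dqx1, Spag1, Apob, Gimd1, Anks4b and Amdhd1.

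**Figure D1:**
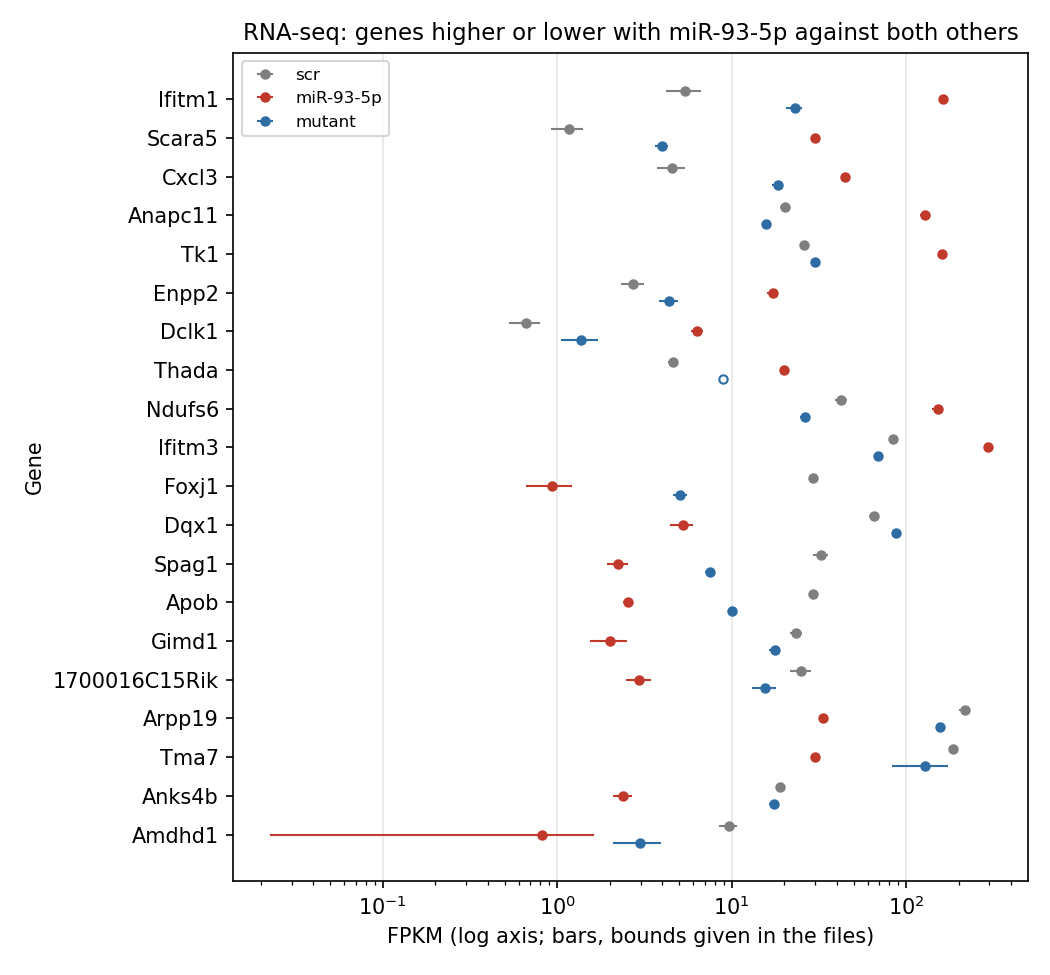
FPKM (log axis) of the 20 RNA-seq genes named for the largest changes in miR-93-5p, with 1 point per library and bars for the bounds in the files; the open point marks a bound that could not be used. miR-93-5p lies above both other libraries from Ifitm1 (163) to Ifitm3 (293) and below them from Foxj1 (0.935) to Amdhd1 (0.817).

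The mutant and miR-93-5p libraries shared many differences from scr. Against scr alone, miR-93-5p had 250 genes higher and 324 lower, and the mutant had 222 higher and 306 lower. Of the 324 lower genes 172 (53.1%) were also lower in the mutant, where independent sets would share 11.8. Counting noise drawn in all 3 libraries around 1 level per gene would give 0.24. Of the 250 higher genes 101 (40.4%) were shared, against 6.60 and 2.35. The scr library enters both ratios and could not be split. Its own transcript models enter both ratios too and were not part of the simulated noise, so their share of these genes was not measured. The scr library itself stood at least 2-fold above both others for 172 genes and below for 101, and the mutant for 47 and 52. Across 8414 genes, which are not independent replicates, the correlation of log FPKM was 0.969 between miR-93-5p and mutant, 0.947 between scr and mutant and 0.942 between scr and miR-93-5p. Counting noise alone would give 0.11 higher and 1.15 lower genes in miR-93-5p against both others.

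Hepatocyte and lipid synthesis genes were the lists that stood apart against scr. Of 8 measured hepatocyte markers the median log2 ratio was -1.14 over scr and -0.71 over mutant, both at percentile 0, and 2 of the 8 were at least 2-fold lower than in both. The mutant itself had a median of -0.41 over scr at percentile 0.99, with 3 of the 8 at least 2-fold lower. Hnf4a, a master regulator of the hepatocyte, was at 7.22 FPKM against 40.6 in scr and 27.4 in mutant. Foxa3 was at 1.94 against 4.21 and 5.27. The keratin gene Krt8 was at 230 against 658 and 283, and Cebpa was at 5.17 against 15.3 in scr and 3.00 in mutant, where it lay below miR-93-5p. Of 21 genes of cholesterol and fatty acid synthesis the median was -0.56 over scr and -0.39 over mutant, both at percentile 0, and -0.29 for mutant over scr at percentile 0.08. Of the 21, 1 was at least 2-fold lower than in both. Squalene synthase Fdft1 was at 19.3 FPKM against 55.3 and 40.6, Sqle at 44.8 against 98.5 and 63.6, and Idi1 at 24.4 against 42.4 and 34.5. In implied fragments the hepatocyte medians were -1.28 over scr and -1.41 over mutant, and those of lipid synthesis -0.39 and -0.035.

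In the main comparison, inflammatory and interferon genes stood apart over the mutant and not over scr. The 16 inflammation and NF-kB genes had a median of 0.59 over mutant at percentile 100 and of 0.16 over scr at percentile 78.1, and the mutant itself lay at -0.59 against scr. Ccl7 was at 113 FPKM against 39.0 in scr and 23.1 in mutant, Cxcl5 at 254 against 83.2 and 50.7, and Cxcl1 at 304 against 151 and 63.3. In implied fragments the list medians were 0.27 over mutant and -0.14 over scr, and the log2 ratios over scr were 1.28 for Ccl7, 0.26 for Cxcl5 and -0.28 for Cxcl1. The 14 interferon response genes had medians of 0.23 over scr at percentile 94.3 and 0.58 over mutant at percentile 100, with Bst2 at 102 FPKM against 42.8 and 68.0. Genes of the unfolded protein and amino acid stress response had medians of 0.13 over scr and -0.48 over mutant, at percentiles 75.8 and 0, and in implied fragments of 0.46 over scr, at percentile 99.78, and -0.21 over mutant. Trib3 stood at 2.99 FPKM in scr, 9.28 in miR-93-5p and 25.8 in mutant, and Chac1 at 2.38, 5.97 and 22.6. Mesenchymal and matrix genes had medians of 0.00 over scr and 0.39 over mutant, at percentiles 40.3 and 99.99. Fn1 was at 41.7 FPKM against 23.6 and 4.17, and Thbs1 at 2.13 against 22.7 and 1.07. Glycolysis and hypoxia genes had medians of 0.10 and 0.29, the latter at percentile 99.99.

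Reported targets and tumour suppressors, the subject of the series, did not stand below other genes. The 39 measured reported targets of miR-93-5p or its family had a median of 0.039 over scr (percentile 56.2) and 0.10 over mutant (97.3). Cdkn1a was at 46.2 FPKM (31.2 to 61.3) in miR-93-5p against 34.5 (33.0 to 36.1) in scr and 48.5 (44.3 to 52.6) in mutant, and its implied fragments were 37.7, 1993 and 547. The 2-fold limit against scr was passed by Pdcd4 alone among these targets, at 27.4 FPKM against 56.5, with 21.7 in mutant. The 34 classical tumour suppressors had a median of 0.074 over scr (percentile 72.5) and 0.12 over mutant (97.7), and Cdkn2c was at 43.5 FPKM against 14.5 in scr and 38.5 in mutant. Mcm7 had no matched locus in the RNA-seq libraries.

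Among the other lists, medians over scr were 0.20 for PI3K-Akt-mTOR signalling, 0.12 for TGF-beta and BMP signalling, 0.11 for p53 response, -0.036 for cell cycle and replication, -0.054 for Wnt signalling, 0.15 for Hippo signalling, 0.14 for apoptosis regulators, 0.29 for biliary and progenitor markers, -0.10 for ribosomal proteins and 0.082 for abundant constitutive genes. Chromatin enzyme lists gave -0.068 for H3K4, 0.089 for H3K27, -0.068 for H3K9 and -0.12 for Polycomb and DNA methylation, and microRNA machinery gave -0.10. Their percentiles over scr lay between 5.46 and 97.0. In implied fragments the H3K4 enzymes stood below scr, at -0.28 and percentile 1.42. Over mutant, apoptosis regulators stood above (0.18, percentile 99.57) and ribosomal proteins below (-0.12, percentile 1.26). Biliary markers moved apart, with Cdh1 at 1.52 FPKM against 30.7 in scr and 3.87 in mutant and Spp1 at 1076 against 531 and 1077. No endothelial marker or mitochondrial transcript and 1 leukocyte marker, Csf1r (1.16 FPKM against 7.63 and 1.82), was measured.

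**Figure D2:**
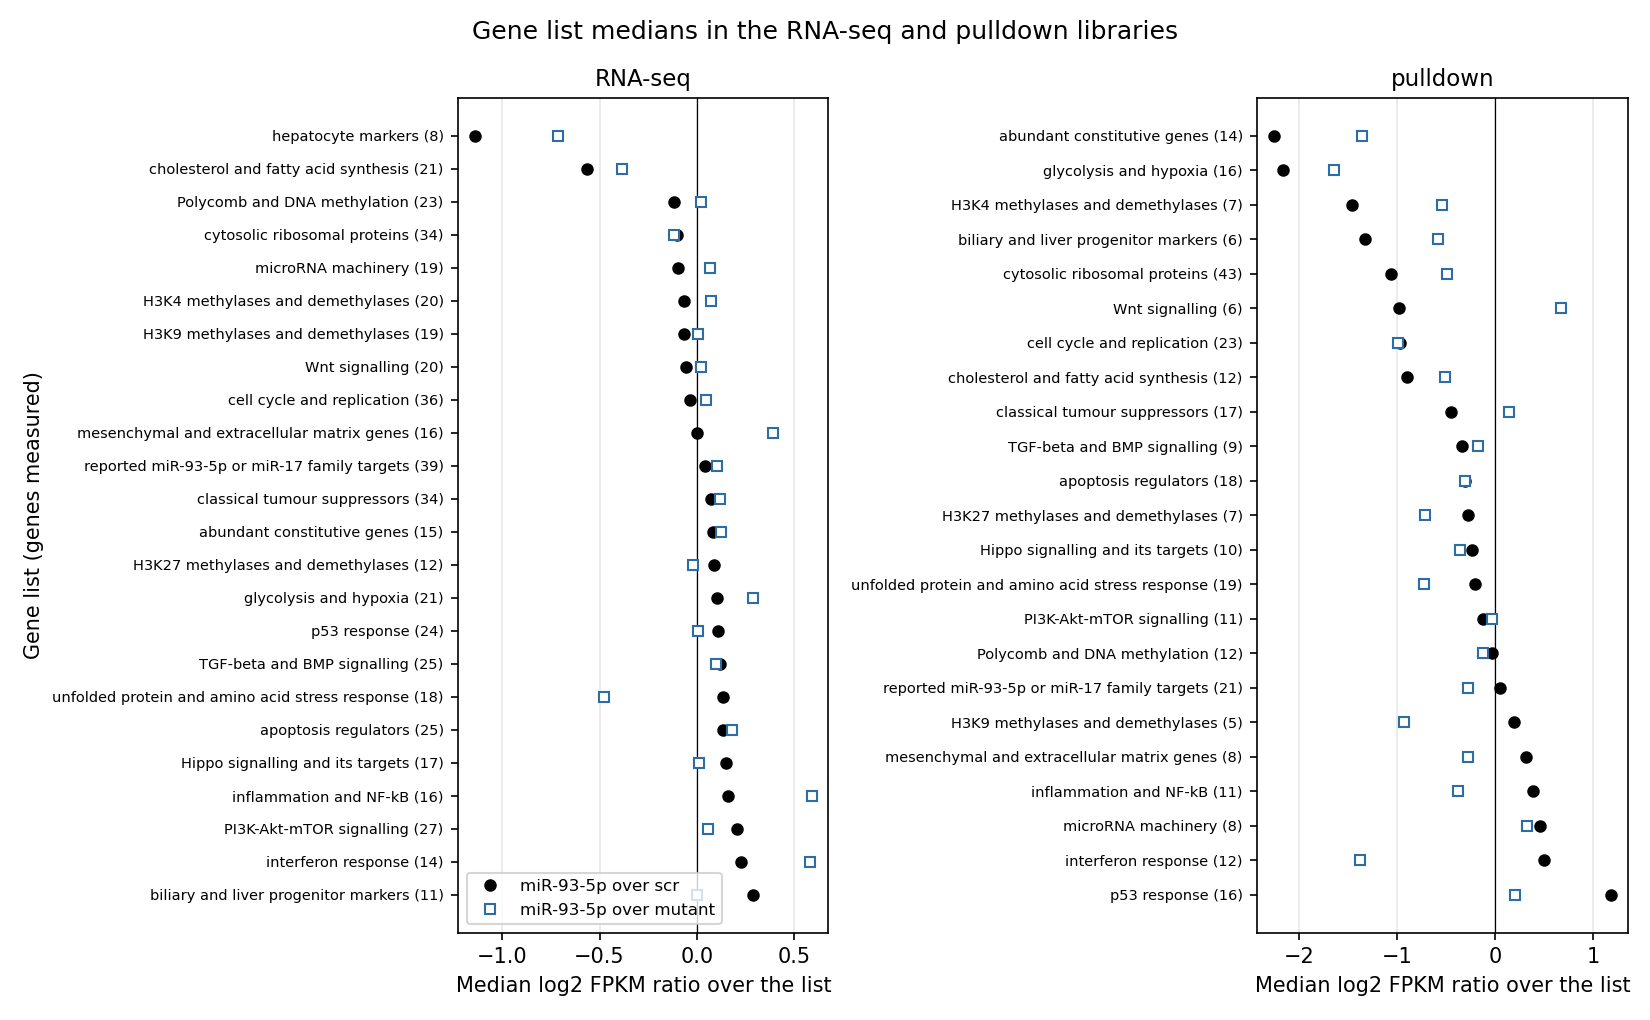
Median log2 FPKM ratio of each gene list in the RNA-seq (left) and pulldown (right) libraries, with the number of genes measured in brackets, for miR-93-5p over scr (filled circles) and over mutant (open squares). Hepatocyte markers (-1.14) and lipid synthesis (-0.56) lie lowest in RNA-seq, and p53 response (1.18) lies highest in the pulldown over scr.

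The pulldown comparison asked which mRNAs were recovered with miR-93-5p more than with its mutant or with scr. Of 5241 genes, 85 were at least 2-fold enriched and 626 at least 2-fold depleted in the miR-93-5p pulldown against both others. E2f1, a cell cycle transcription factor on the list of reported targets, was at 78.4 FPKM (74.0 to 82.7) against 8.71 (7.61 to 9.81) in scr and 30.7 (28.7 to 32.8) in mutant. The other reported target past 2-fold against both was Trp53inp1, at 10.3 FPKM against 2.34 and 3.90. The phosphatase gene Dusp2 was at 22.4 against 1.78 and 3.43, the nucleosome-binding genes Hmgn3 at 134 against 12.9 and 27.3 and Hmgn1 at 4154 against 627 and 2067, and Cacfd1 at 110 against 6.29 and 30.9. Zbed4 was at 50.4 against 5.45 and 22.4. These genes were also enriched at least 2-fold over both others in scaled implied fragments. Before scaling, E2f1, Cacfd1 and Zbed4 were under 2-fold over mutant, with 1289 against 898, 909 against 557 and 188 against 101. For Hmgn1 the 2 measures lay far apart. Its log2 ratios over scr and mutant were 5.66 and 5.57 in implied fragments and 2.73 and 1.01 in FPKM.

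The most enriched gene in FPKM was Svip, at 51.7 against 1.63 in scr and 8.52 in mutant, with implied fragments of 149, 26.9 and 337. Mkks, Brms1l, Knop1 and Efcab11 lay between 22.3 and 291 FPKM in miR-93-5p, with log2 ratios over scr from 3.04 to 3.92, and their log2 ratios over mutant in implied fragments were all below 0. The splicing gene Snrpf was at 11843 FPKM against 812 and 4491, and the chaperonin gene Hspe1 at 7495 against 1058 and 3400. Son was at 108 against 14.6 and 3.25 and Rnpc3 at 54.8 against 6.42 and 4.10, and both had log2 ratios below 0 in implied fragments. In all, 39 of the 85 enriched genes and 197 of the 626 depleted genes passed in implied fragments too. FPKM was not scaled, so scaling and model length both enter the difference between these counts. Counting noise alone would give 0.64 enriched and 5.74 depleted genes.

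Abundant mRNAs were low in the miR-93-5p pulldown. Actb was at 28.8 FPKM against 613 in scr and 83.7 in mutant, and the glycolytic enzyme Pkm at 66.2 against 1293 and 359. The most depleted genes also held Pet100 at 5.82 against 193 and 87.3, with log2 ratios in implied fragments of -0.036 over scr and 0.45 over mutant. The transglutaminase Tgm2 was at 2.02 against 46.3 and 15.0, and Tsr3 at 2.49 against 57.3 and 60.04. In implied fragments Actb was at log2 ratios of -1.37 over scr and -0.42 over mutant, so it did not pass over mutant. Pkm (-1.27 and -1.06), Tgm2 and Tsr3 were at least 2-fold below both others in that measure. The median log2 ratio of all 5241 genes was -0.48 over scr and -0.43 over mutant. With each library rescaled to a median of 0, 256 genes were enriched and 255 depleted. In 4 equal groups by RNA-seq abundance the median over scr was -0.017 in the lowest, then -0.40, -0.68 and -1.05. In implied fragments the same groups were at 0.27, -0.086, -0.12 and -0.068. Between the lowest and the highest group the median over mutant went from -0.15 to -0.76 in FPKM and from -0.030 to 0.13 in implied fragments. The miR-93-5p library held loci with a median span of 2121 bp against 9177 in scr and 9086 in mutant, and 6313 genes were matched in it against 9060 and 8946.

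**Figure D3:**
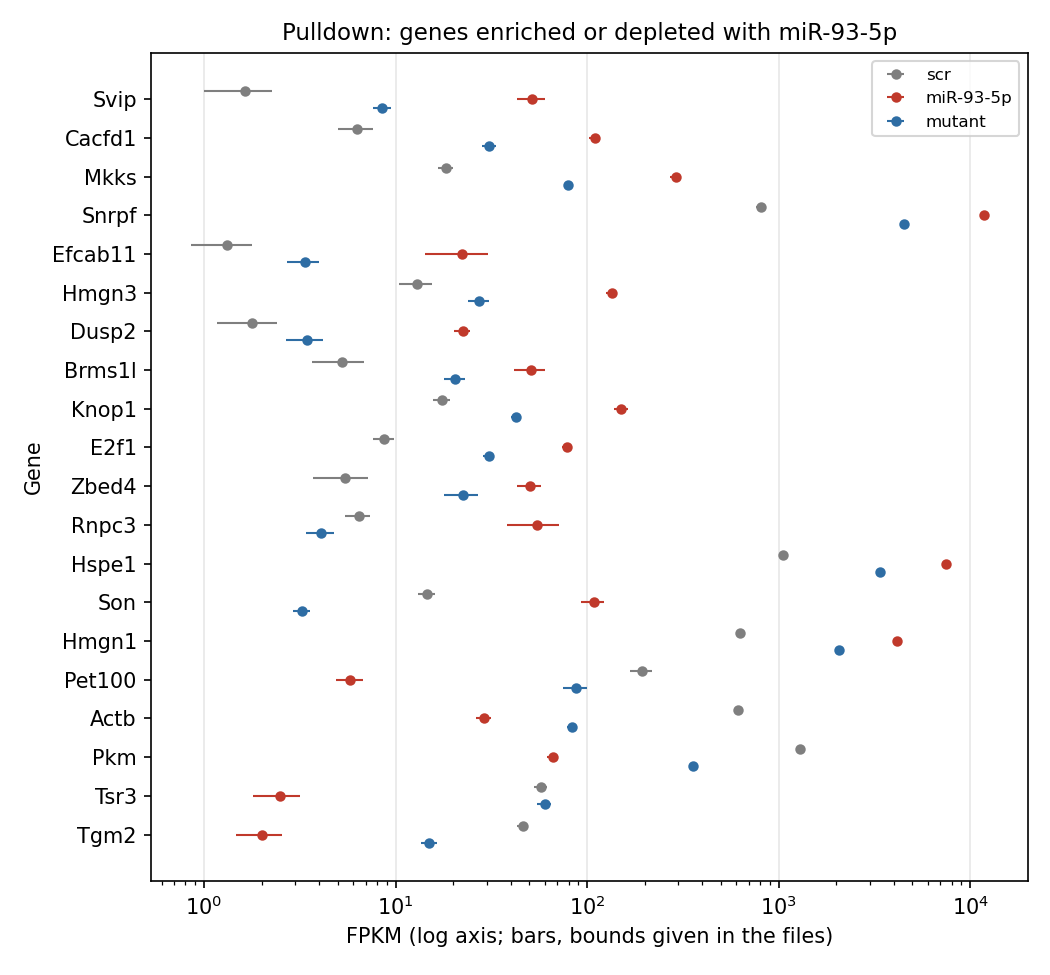
FPKM (log axis) of the 15 most enriched and 5 most depleted genes of the miR-93-5p pulldown, with 1 point per library and bars for the bounds in the files. E2f1 stands at 8.71 in scr, 78.4 in miR-93-5p and 30.7 in mutant, and Actb at 613, 28.8 and 83.7.

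Genes of the p53 response were high in the miR-93-5p pulldown, with a median of 1.18 over scr at percentile 100 and of 0.21 over mutant at percentile 99.5. Of 16 measured members 10 were at least 2-fold above scr, including Btg2 at 31.9 FPKM against 3.66, Gadd45a at 117 against 23.5, Bbc3 at 27.8 against 8.52 and Mdm2, the p53 antagonist, at 59.8 against 19.3. The mutant pulldown was also above scr for this list, with a median of 0.81 at percentile 98.7, and held Btg2 at 35.2 and Mdm2 at 29.1. In implied fragments the medians were 1.13 over scr and 0.34 over mutant. Interferon response genes had a median of 0.51 over scr at percentile 98.9 and of -1.37 over mutant at percentile 0.04, with Isg15 at 55.7 FPKM against 8.35 in scr and 143 in mutant. Over scr the list did not stand apart in implied fragments (percentile 83.8) or with an overlap of at least 0.9 (93.1). Glycolysis and hypoxia genes were at -2.16 and abundant constitutive genes at -2.25 over scr, both at percentile 0, and at -0.0085 and -0.45 in implied fragments. With an overlap of at least 0.9 they were at -1.47 (percentile 2.73) and -0.94 (21.1) and did not stand apart. Ribosomal protein genes were at -1.06 over scr at percentile 0.58, and at 0.44 in implied fragments. Because only implied fragments were scaled, such shifts between the 2 measures mix scaling with model length.

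The 21 measured reported targets had a pulldown median of 0.049 over scr (percentile 94.6) and -0.27 over mutant (60.9). Cdkn1a was at 56.5 FPKM (45.7 to 67.3) against 54.6 (48.1 to 61.2) in scr and 32.9 (30.8 to 35.1) in mutant, with log2 ratios in implied fragments of -0.70 over scr and -2.26 over mutant. Mcm7 was at 149 FPKM in scr and 78.1 in mutant and had no matched locus in miR-93-5p. Medians over scr were -0.45 for classical tumour suppressors, where Socs1 stood at 36.0 FPKM against 2.97 and Trp53 at 5.50 against 67.5, -0.12 for PI3K-Akt-mTOR, -0.33 for TGF-beta and BMP, -0.97 for Wnt and -0.24 for Hippo signalling, -0.30 for apoptosis regulators and -0.96 for cell cycle and replication. They were -1.46, -0.27 and 0.20 for the H3K4, H3K27 and H3K9 enzymes, -0.026 for Polycomb and DNA methylation, 0.46 for microRNA machinery, -1.32 for biliary markers, 0.32 for mesenchymal genes, 0.39 for inflammation, -0.20 for the unfolded protein response and -0.89 for lipid synthesis, with percentiles from 5.00 to 97.4. In implied fragments inflammation (1.10, percentile 98.5) and Hippo signalling (1.05, 98.8) stood above scr. Over mutant, microRNA machinery (0.33, percentile 98.3) and Wnt signalling (0.68, 99.75) stood above, and cell cycle (-0.99, 2.02), glycolysis (-1.64, 0.02) and constitutive genes (-1.35, 0.67) below. Of hepatocyte markers 4 were measured, too few for a median, and no endothelial, leukocyte or mitochondrial gene was.

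The next comparison asked whether mRNAs recovered with miR-93-5p were lower when it was overexpressed. The 75 pulldown-enriched genes with an RNA-seq value had a median RNA-seq log2 ratio of -0.066 over scr at percentile 4.15 and of -0.0071 over mutant at percentile 28.8. Over scr the percentile was 1.60 with a pseudocount of 0.1 and 22.7 in implied fragments. Over scr, 4 of them were at least 2-fold lower and 2 at least 2-fold higher. E2f1 was at 16.4 FPKM in RNA-seq against 22.5 in scr and 14.9 in mutant. No enriched gene was among the RNA-seq genes lower than both others, where 0.616 would be shared if the sets were independent. Cenpw and Zfp938, named after their values were seen, were among the higher genes.

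Histone marks were compared between scr and miR-93-5p. H3K4me3, a mark of active promoters, had 14595 peaks over 36.9 Mb in scr and 16173 over 39.97 Mb in miR-93-5p. H3K9me3, a mark of heterochromatin, had 15888 peaks over 21.6 Mb and 25879 over 39.2 Mb. H3K27me3, the Polycomb mark, had nearly equal numbers, 44412 and 43501, and its covered length was 60.01 Mb in scr and 23.7 Mb in miR-93-5p. The median width of its peaks was 1049 bp in scr and 473 bp in miR-93-5p. Of the scr peaks 94.9% for H3K4me3, 34.0% for H3K27me3 and 72.3% for H3K9me3 overlapped a miR-93-5p peak, and of the miR-93-5p peaks 86.1%, 44.9% and 42.9% overlapped a scr peak. Read depth is unknown for these libraries, and each had its own peak call.

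**Figure D4:**
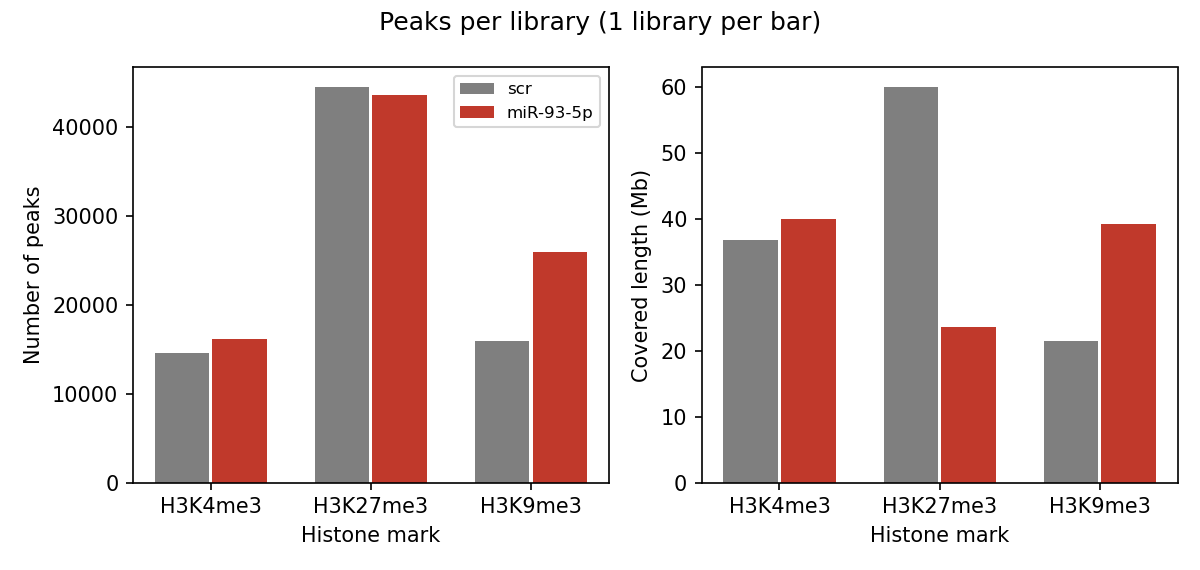
Number of peaks (left) and length covered by peaks in Mb (right) for each histone mark in scr (grey) and miR-93-5p (red), 1 library per bar. H3K27me3 covers 60.01 Mb in scr and 23.7 Mb in miR-93-5p with 44412 and 43501 peaks.

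The strongest H3K4me3 peak found in miR-93-5p alone lay over Ifitm1 (mm9 chromosome 7, 148153603 to 148158231, score 2182), the gene with the largest rise in RNA-seq. A peak over the ubiquitin ligase gene Rnf128 (chromosome X, 136097638 to 136100660) had a score of 713. H3K4me3 peaks of scr alone lay over Cdsn (chromosome 17, 35688679 to 35691597, score 2402), Msx2 (chromosome 13, 53566056 to 53568556, 1973), Hoxd9 (chromosome 2, 74535291 to 74537235, 1579) and 3830406C13Rik (chromosome 14, 13116484 to 13117902, 1567). H3K27me3 peaks of scr alone lay over the ephrin gene Efna3 (chromosome 3, 89122273 to 89128630, score 1544), Wnt7a (chromosome 6, 91358309 to 91365006, 1193) and Arid3a (chromosome 10, 79390628 to 79396862, 1109), and the strongest of miR-93-5p alone over Ccr6 (chromosome 17, 8430120 to 8434116, 335). H3K9me3 peaks of miR-93-5p alone lay over Tpd52 (chromosome 3, 8977002 to 8985152, score 931) and Hoxc9 (chromosome 15, 102805159 to 102808351, 715), and one of scr alone over Ly6a (chromosome 15, 74824027 to 74825896, 302).

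Of 18479 gene loci, 239 had H3K4me3 in miR-93-5p alone and 185 in scr alone, 685 and 937 had H3K27me3, and 1331 and 437 had H3K9me3. Among the lists, hepatocyte genes Pck1, Tdo2, Fgg, Fgb and Cyp1a2 had H3K27me3 in scr alone and Cyp2e1 in miR-93-5p alone. Scd1, a gene of fatty acid synthesis, had H3K4me3 in scr alone. Pdcd4 and Nr2c2 of the reported targets had H3K9me3 in scr alone, and Bmpr2 and Ncoa3 in miR-93-5p alone. Genes with H3K27me3 in miR-93-5p alone had a median RNA-seq log2 ratio of -0.42 over scr (45 genes, percentile 0). Over mutant they stood above other genes, at 0.17 and percentile 99.1. Those with it in scr alone were at -0.16 over scr (124 genes, percentile 0.23) and at 0.034 over mutant (percentile 42.0). Genes with H3K4me3 in miR-93-5p alone had a median of -0.46 over scr (17 genes, percentile 0.10) and of 0.062 with peaks assigned by midpoint. Those with it in scr alone had a median of -0.14 (14 genes). Genes with H3K4me3 in neither library also stood below, at -0.18 over scr (100 genes, percentile 0.2). Those with H3K9me3 in miR-93-5p alone had a median of 0.039 and in scr alone of 0.031.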

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

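All tests in this part were chosen after the results were seen.

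The miR-93-5p pulldown held 1514 assembled loci outside annotated genes, a signal not used in the comparisons and above the 607 in the scr pulldown and the 616 in the mutant pulldown. These loci made up 8.40% of all loci in miR-93-5p, 3.97% in scr and 4.16% in mutant, and carried 5.07%, 7.12% and 1.04% of the implied fragments.

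The hepatocyte and sterol lists had FPKM medians below 0 over scr and over mutant in RNA-seq, with 2 of 8 and 1 of 21 genes at least 2-fold below both. Transcript models that differed only in the length used for FPKM would leave no difference in implied fragments. The hepatocyte list had a median of -1.41 over mutant in that measure, so model length alone does not account for it. Bounds also depend on how isoforms share fragments, so other effects of separate assembly stay open for these 8 genes. Differences in model length may account for the sterol list over mutant, which had a median of -0.035 in implied fragments. A scr library that alone stood apart would leave the hepatocyte list level between miR-93-5p and mutant, where the median was -0.71. An effect of the miR-93-5p sequence and a difference between cultures cannot be told apart for the hepatocyte list, because 6 of the 24 lists stood apart between the mutant and scr libraries as well and each condition had 1 library.

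Abundant mRNAs such as Actb and Pkm were low in the miR-93-5p pulldown in FPKM. Counting noise does not account for the depleted genes, since it gave 5.74 where 595 of the same 4947 were seen, and whether lower depth shortened the assembled models was not tested. Separately assembled models may account for the gap between the most and the least abundant of 4 groups over mutant, where its share left in implied fragments was -0.267, while over scr the share was 0.327, a value that neither removes nor keeps the pattern. Capture of miR-93-5p targets in place of abundant mRNAs stays open too, because the reported targets lay at percentile 60.9 over mutant, inside the range of random lists. With 1 library each, models and capture cannot be told apart over scr.

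H3K27me3 peaks covered far less length in miR-93-5p at a nearly equal number. A peak call with a smaller minimum width may be a source of part of the difference. The smallest H3K27me3 peak was 0.573 times as wide in miR-93-5p as in scr, while the ratio was 1.33 for H3K4me3 and 1.06 for H3K9me3. A smaller minimum alone would not narrow the widest peaks, and the widest was 22511 bp in scr and 4929 bp in miR-93-5p. Fewer reads or weaker enrichment cannot be told apart from a real change, because read depth is unknown. The number of peaks was 0.979 times that of scr, and 0.699 times with only peaks at or above the median score. Peak scores depend on both depth and enrichment. Their median was 65.1 in miR-93-5p and 76.8 in scr, and their top decile 114 and 193. A loss of the mark with a rise of the genes that lost it cannot be told apart from none, because their RNA-seq median was -0.16 over scr and 0.034 over mutant, where no mark was measured.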

How the results depend on the processing

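Tests with other matching limits, genes of every biotype, implied fragments, both measures together, peak midpoints or a library left out were chosen after seeing the data; the others were planned. Over 493 alternative values, 124 of them for the main results, 71 of the 124 stayed within their range and 53 did not; the cause was not tested unless stated. Some alternatives kept only peaks at or above the median score of the mark, called stronger peaks below. With these, covered length in miR-93-5p over scr was 1.05 for H3K4me3, 0.289 for H3K27me3 and 2.06 for H3K9me3. For H3K4me3 the median score was 3100, the score of 59.8% of scr and 54.7% of miR-93-5p peaks. A gene could thus gain or lose strong H3K4me3 because the peak of a single library reached that common score. With overlap limits of 0.9, under which 6406 and 3113 genes were tested, RNA-seq had 26 genes higher and 45 lower and the pulldown 50 enriched, all among those first counted, and 3 pulldown lists stood apart, 2 of them among the 5 first counted. Passing 2-fold in both FPKM and implied fragments left 17, 37 and 39, and implied fragments alone gave 162, 305 and 260, of which 17, 37 and 39 were among those first counted. Without the mutant library the counts were 250, 324 and 617, and without the scr library 156, 148 and 255, since these drop a condition. Rescaling the pulldown to a median of 0 gave 256 enriched genes, whose RNA-seq median was 0.014. Lists that stood apart in RNA-seq numbered 2, then 3 with a mean FPKM of at least 5, 4 in implied fragments and 10 without scr. Of the pulldown lists that stood apart over scr, ribosomal proteins turned to 0.44 in implied fragments and interferon response to -1.37 without scr; lists that did not stand apart changed sign as well, such as Hippo signalling to 1.05 in implied fragments and Wnt signalling to 0.68 without scr.

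Shared peaks under a reciprocal overlap of 50% were 92.7% of scr and 83.7% of miR-93-5p peaks for H3K4me3, 10.2% and 10.4% for H3K27me3, and 55.8% and 34.3% for H3K9me3. With equal numbers of top-scoring peaks they were 92.2% and 92.3% for H3K4me3 and 59.8% and 56.4% for H3K9me3. With only the stronger peaks, 453 genes gained H3K27me3 and 241 lost H3K9me3. A 5 kb extension gave 1709 genes that lost H3K27me3, and midpoints gave 552 that gained and 408 that lost H3K4me3.

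The RNA-seq median of genes that gained H3K27me3 was -0.26 with stronger peaks, -0.58 with a pseudocount of 0.1, -0.30 with midpoints, -0.58 in implied fragments and reversed to 0.17 without scr. Genes that lost it gave 0.034 without scr, reversed, and -0.10 in implied fragments. Genes that gained H3K4me3 gave -0.087 with stronger peaks, 0.062 with midpoints and 0.038 without scr, both reversed, and -0.25 in implied fragments. Genes that lost H3K4me3 gave 0.069 with stronger peaks, 0.045 with midpoints, 0.046 without scr and 0.58 in implied fragments. The sets from stronger peaks shared only 10 of the genes that gained and 9 of those that lost H3K4me3. Genes that gained H3K9me3 gave 0.10 with stronger peaks and 0.065 without scr, and genes that lost it 0.086 with stronger peaks. Seed matches of 7 bases in the UTR, of 8 bases with A opposite position 1 and of 7 bases anywhere in the transcript were not run. No paired analysis was possible because each group had 1 library and no result came from a test. Implied fragments were fewest in the miR-93-5p pulldown, at 3814082, which limits genes with low counts there.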

Other observations

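Genes with H3K4me3 in scr alone were assembled in scr and not in miR-93-5p RNA-seq more often than genes with the mark in both. These tests were chosen only after the data were seen. Of 185 genes with H3K4me3 in scr alone, 38 (20.5%) were assembled in the scr RNA-seq library and had no overlapping locus in miR-93-5p, and 4 showed the reverse. Among 10216 genes with H3K4me3 in both conditions the numbers were 92 (0.901%) and 40. The median scr FPKM of genes with an RNA-seq ratio was 2.30 (14 genes, scr alone) and 15.8 (8283 genes, both). No set matched on abundance was compared. Most of the 38 lay low, with a median of 2.25 FPKM in scr and a lower bound of 0 for Fsd1l, Matn2 and Gm609. The highest was Rtl8b at 26.5 FPKM in scr, and Smagp was at 8.79. Others with more included the kinase gene Pdk3 at 8.94 FPKM in scr, the tetraspanin Tspan13 at 8.53, Tnfrsf23 at 6.06 and the homeobox gene Msx1 at 2.80. In the mutant RNA-seq library 31 of the 38 were absent as well, among them Pdk3, Tspan13, Tnfrsf23 and Msx1. Rtl8b and Smagp had an overlapping locus there. No histone mark was measured in mutant cells. Of the 239 genes with the mark in miR-93-5p alone, 4 (1.67%) were assembled in miR-93-5p and not in scr, where the share among genes with the mark in both was 0.392%, and 12 (5.02%) the other way. Over all 18479 genes, 285 were assembled in scr and not in miR-93-5p and 89 the other way.

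A few single genes outside the largest changes are given here without a common theme. The cadherin gene Cdh1 was at 30.7 FPKM in scr, 1.52 in miR-93-5p and 3.87 in mutant, the apoptosis gene Bmf at 32.3, 6.35 and 5.55, and Ankrd1, a target of Hippo signalling, at 44.3, 125 and 107. Among genes that no locus of the miR-93-5p RNA-seq library overlapped while both others held them, the adhesion gene Bcam was at 17.5 FPKM in scr and 17.3 in mutant, and Fhl1 at 6.25 and 0.838. Capn6 at 3.12 FPKM and Gpnmb at 1.70 were assembled in miR-93-5p alone. These genes were chosen after their values were seen, apart from those named by list.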
